A study of Mus musculus with 2 samples.

How the data were processed

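H3K27me3, the trimethylated form of lysine 27 of histone H3 that Polycomb repressive complexes deposit on silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in liver from mouse embryos of day 16.5 (strain B6NCrl). The group has 2 biological replicates, each a pool of livers from male and female embryos with its own biosample record. Both records name the same donor entry in the labels, and they were treated here as separate pools, which every n = 2 and SD rests on. Replicate 2 was made from 41 embryos, and the number behind replicate 1 is not stated in the labels. The labels give a fragment size range of 300 to 500 bp and 2 technical replicates per biological replicate, which were merged before peaks were called. The spread between the replicates therefore covers differences between pools of embryos and library preparation together, and there is no second tissue, stage or treatment to compare with.

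The files used here were the authors' peak lists, on the mm10 build per the labels. The deposited notes also list alignments and signal tracks, which were not among the files at hand. There is 1 list per biological replicate, 1 list called on both replicates pooled, and 1 list, called replicated here, that was derived from the other 3. Per the notes deposited with the lists, each call used the filtered alignments and further input files. The aligner, the peak caller, their versions and the rule behind the replicated list are not given in the sources used here. The deposited lists carry for each peak a display score, which was not used. They also carry the authors' signal value of the peak, which was taken here as a ratio, the fold enrichment over control, from the file type and the range of the values, since no source used here names the caller. The labels list a possible control experiment without saying that it was used. The deposited lists give as well the −log10 of its p-value and q-value as the authors' peak caller wrote them. These are each peak's own values, were not scaled between lists, and were used to describe, rank and filter peaks within a list and to compare the order of regions between lists. Sequencing depth cannot be read from peak lists, so it is unknown here, and no interval that needs it is given. A region without a peak is therefore one that did not pass the authors' threshold, and it may still carry the mark at a lower level.

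Peaks were intersected with GENCODE release M21 gene models and the GRCm38 sequence, the same assembly as mm10, and every peak lay within the length of its chromosome. Only chromosomes that held peaks were used, which were the 19 autosomes and X. A promoter was the interval of 1 kb on each side of any annotated start of a protein-coding transcript, and a gene was called marked when a replicated peak overlapped one of its promoters by at least 1 bp. This gave 21670 protein-coding genes. A gene's fold in a replicate was the highest fold among that replicate's peaks over its promoters, and is given as mean ± SD over n = 2 replicates. The peak can lie at any of the gene's promoters, and for 447 genes the 5′ end of the gene, used in one alternative, had no protein-coding start within 1 kb. Genes side by side can share a peak and then share its fold. A promoter was called CpG-rich when a 500 bp window within it had a GC share of at least 0.55 and a CpG observed to expected ratio of at least 0.75. Replicated peaks within 3 kb of each other were joined into domains.

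Overlap between lists was tested against 1000 random circular shifts of one list within each chromosome (one-sided permutation test). Agreement in fold was measured by Spearman's rho across peaks, which are not independent replicates, with a 95% interval from 1000 bootstraps of chromosomes. Pooled peaks inside and outside the replicated list were compared by sign flips of the differences per chromosome (100000 resamples, two-sided permutation test). The marked share of 24 gene lists was compared with that of all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Of the listed symbols 1, Ahsp, was not matched in the annotation. The gene lists, tests and most alternatives were fixed before the data were examined. The alternatives were other promoter windows (0.5 and 2.5 kb), the list of either replicate alone, the pooled list, peaks with a q-value of 1% or less, at least 500 bp of the promoter covered, rotation of the marks over gene order (10000 rotations, two-sided), CpG-rich promoters alone, and other joining distances and overlap rules. A promoter at the 5′ end of the gene only, autosomes only, peaks that both replicate lists overlap, equal numbers of peaks per replicate, covered bases on X in replicate 2, the marked share of X genes in each replicate and the overlap of peaks at genes marked in 1 replicate alone were added after the data had been seen.

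The genes named were chosen by a rule fixed beforehand. From each list it took the 2 marked members with the highest mean fold over replicates, and in addition a fixed set of liver, blood, housekeeping and developmental genes whether marked or not. It also took the 10 genes outside all lists with the highest mean fold, the genes in the 5 widest domains, and the 3 genes with the highest fold among those marked in only 1 replicate, for each replicate. Other names were chosen after their values were seen, which is said where they occur. The scripts were tested on simulated data. Marks placed on the real genes independently of each other and of the lists gave any call among the lists in 3 of 100 runs. Such marks do not cluster or follow CpG content, so this is not the rate of false calls for the real marks. With most members marked, 400 of 400 planted lists were called. These were the HOX list and the neural, mesodermal and other endodermal factor lists only. Peak overlap was tested on random intervals of an invented chromosome. There 3 of 40 pairs of independent lists and 40 of 40 pairs with planted overlap passed the threshold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.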

Results

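H3K27me3 was profiled in liver from mouse embryos of day 16.5, a stage at which the organ holds hepatoblasts and maturing hepatocytes together with a large population of blood-forming cells. Peaks from 2 biological replicates, each a pool of embryos, were compared with each other, with gene promoters and with lists of genes fixed before the data were examined. The replicate 1 list held 32746 peaks that covered 23.5 Mb (0.894% of the genome), with a median width of 311 bp and a median fold over control of 3.57. The replicate 2 list held 49437 peaks that covered 30.8 Mb (1.17% of the genome), with a median width of 278 bp and a median fold of 3.48. The mean over replicates was 41091.5 ± 11802.3 peaks and 27.2 ± 5.15 Mb (SD, n = 2). The authors' pooled list held 28119 peaks over 25.1 Mb, and their replicated list held 22559 peaks over 23.8 Mb with a median width of 456 bp. Folds are the authors' signal values for each peak, taken here as folds over control. Sequencing depth is unknown for these lists, so the larger number of peaks in replicate 2 cannot be set against its number of reads.

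The first question was how far the mark lay in the same places in both pools. Of the replicate 1 peaks, 76.0% overlapped a replicate 2 peak by at least 1 bp, where random shifts gave 2.11% on average. Of the replicate 2 peaks, 44.7% overlapped a replicate 1 peak, where shifts gave 1.43%. The Jaccard index, the bases both lists covered over the bases either covered, was 0.579. None of 1000 shifts reached the observed overlap in either direction (one-sided permutation test, p = 0.000999, the smallest these shifts can give). Regions that were strong in one pool tended to be strong in the other, with a Spearman's rho for fold of 0.656 (95% interval 0.642 to 0.669) across 19649 replicated peaks that overlapped a peak in both replicates. This rho is across peaks, which are not independent replicates. On autosomes alone, the share of replicate 2 peaks found in replicate 1 was 49.4%.

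All 22559 replicated peaks were peaks of the pooled list, of which they made up 80.2%. They were stronger and wider than the pooled peaks left out, with a median fold of 3.66 against 2.88 and a median width of 456 bp against 215 bp. The direction was the same on 20 of 20 chromosomes for both measures (two-sided permutation test by sign flips over chromosomes, p = 2.0e-05 for each). Replicated peaks that overlapped no replicate 1 peak numbered 2440, and 485 overlapped no replicate 2 peak. Passing into the replicated list thus did not require an overlapping peak in both replicate lists, and the lists are nested by construction, so this comparison is no measure of independent agreement.

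H3K27me3 was concentrated at gene promoters. Promoters held 35.5% of the bases under replicated peaks and 2.43% of the genome, a ratio of 14.6. Exons outside promoters held 7.13% of the peak bases, introns 26.8% and intergenic sequence 30.5%, which is 3.05, 0.761 and 0.509 times their share of the genome. By number, 34.1% of replicated peaks overlapped a promoter, against 3.81% for shifted peaks (one-sided permutation test over 1000 shifts, p = 0.000999, the smallest they can give). The same share was 28.8% for the replicate 1 list and 21.4% for the replicate 2 list.

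In all, 5033 of 21670 protein-coding genes (23.2%) had a marked promoter. The replicate 1 list marked 5269 genes and the replicate 2 list 5811, or 25.6% ± 1.77 of genes (SD, n = 2). Both replicates marked 5073 genes, 196 were marked in replicate 1 alone and 738 in replicate 2 alone, and Cohen's kappa between the replicates was 0.887. Of the 738 genes, 130 lay on chromosome X. The strongest genes marked in replicate 1 alone were Olfr1416 (chromosome 1, fold 11.2), Psmb3 (chromosome 11, fold 8.46) and Clvs1 (chromosome 4, fold 4.46). Those marked in replicate 2 alone were Racgap1 (chromosome 15, fold 8.61), 2300002M23Rik (chromosome 17, fold 6.40) and Gm5475 (chromosome 15, fold 6.26). Each of these 6 values comes from 1 replicate and carries no error. For Psmb3, Racgap1, 2300002M23Rik and Gm5475 the peak overlapped a peak of the other replicate that lay just outside the promoter window, so these calls differ by where a peak ended. Over all genes marked in 1 replicate alone this held for 10 of 196 in replicate 1 and 22 of 738 in replicate 2.

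Genes with a promoter rich in CpG dinucleotides, the promoter class bound by Polycomb complexes in many mammalian cells, were marked more often than other genes. Both calls count any promoter of a gene, so the CpG-rich promoter and the marked one can differ. Of 11447 genes with a CpG-rich promoter 3755 (32.8%) were marked, against 1278 of 10223 (12.5%) of the rest, an odds ratio of 3.42 (95% interval 3.18 to 3.67; two-sided Fisher's exact test, p = 2.7e-284). The test treats genes as independent, although genes side by side can share a peak, so this interval and p-value are likely too narrow. With the list of one replicate alone the odds ratio was 3.19 for replicate 1 and 2.70 for replicate 2. Where the CpG ratio required was lowered to 0.6 the odds ratio was 7.36, with 4486 of 13256 genes (33.8%) marked against 547 of 8414 (6.50%). The odds ratio thus grew because fewer of the remaining genes were marked, while the share among CpG-rich genes changed little.

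In the replicated list the widest stretches of H3K27me3 lay over the 4 HOX clusters, whose genes encode the homeodomain factors that pattern the body axis. Joining replicated peaks gave 8254 domains with a median width of 2336 bp (1539.5 bp with the replicate 1 list alone and 1136 bp with the replicate 2 list alone), and the 4 widest were the HOX clusters. The HOXC domain spanned 148 kb of chromosome 15 (102903937 to 103051818) and held Hoxc13, Hoxc12, Hoxc11, Hoxc10, Hoxc9, Hoxc8, Hoxc6, Hoxc5 and Hoxc4. The HOXA domain spanned 131 kb of chromosome 6 (52147119 to 52278313) and held Hoxa1 to Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13, besides Gm28308 and 5730596B20Rik. The HOXD domain spanned 124 kb of chromosome 2 (74645102 to 74768973) and held Evx2, Hoxd13, Hoxd12, Hoxd11, Hoxd10, Hoxd9, Hoxd8, Hoxd4, Hoxd3 and Hoxd1. The HOXB domain spanned 109 kb of chromosome 11 (96249525 to 96358558) and held Hoxb2 to Hoxb9. Peaks covered 86.5%, 87.9%, 88.6% and 91.6% of these domains in turn. The fifth widest domain, 67019 bp of chromosome 8 (12821047 to 12888065) from within Atp11a to within Mcf2l, was under peaks over 42.5% of its length. The replicate 1 list gave the same 5 domains at the top in the same order, while in the replicate 2 list, which joined into 16559 domains, the chromosome 8 domain was 134702 bp wide and ranked between HOXA (139110 bp) and HOXD (129613 bp) and HOXB (127815 bp).

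**Figure D1:**
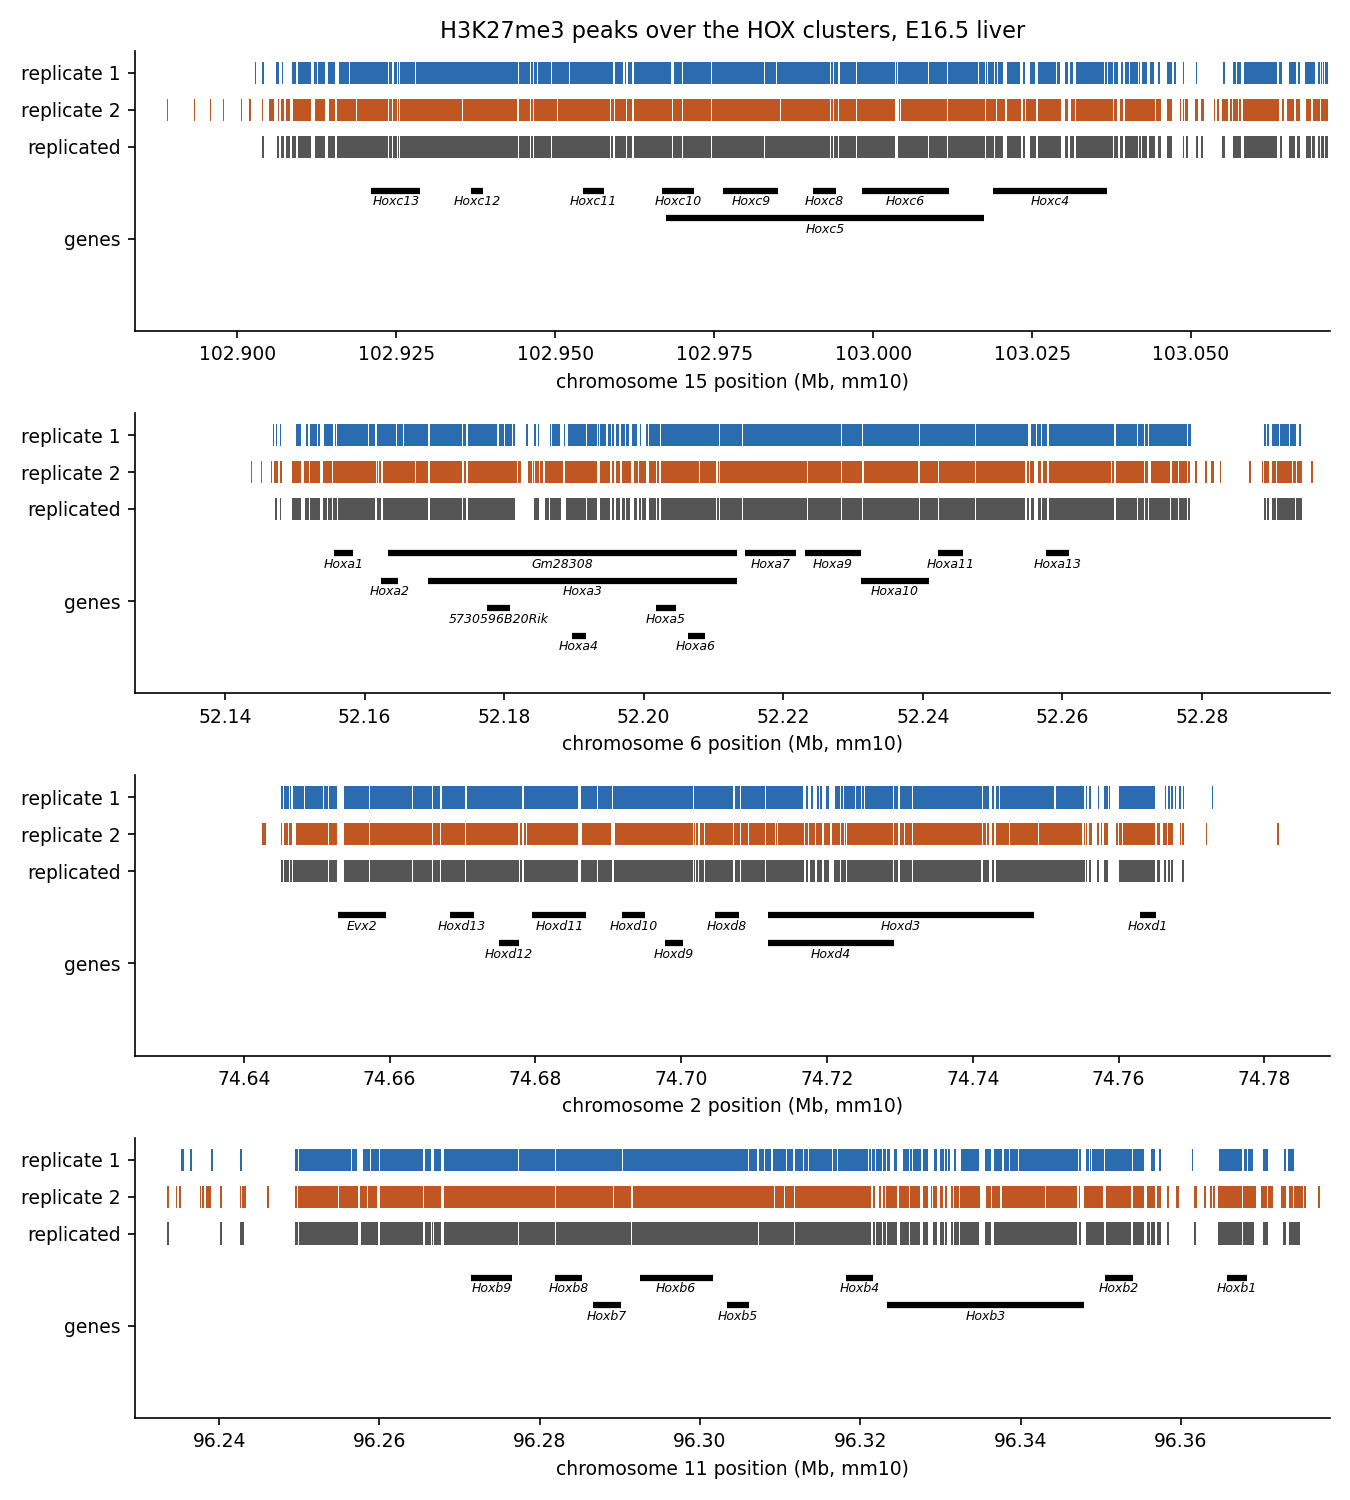
Peaks of each replicate list and of the replicated list over the HOXC, HOXA, HOXD and HOXB clusters, with position in Mb on the horizontal axis and protein-coding genes drawn as black bars. Peaks cover most of each domain in both replicates, and the joined domains of the replicated list are 148, 131, 124 and 109 kb wide.

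The listed transcription factor and signalling genes of development were almost all marked in liver. All 39 HOX genes and all 44 transcription factor genes of neural development were marked in the replicated list and in each replicate, as were 40 of 42 transcription factor genes of mesoderm and limb, 21 of 22 transcription factor genes of other endodermal organs and 40 of 41 genes for developmental signalling ligands and antagonists. The rest of the protein-coding genes were marked in about 23.1% of cases. The exceptions were Myf5 and Myf6, which drive skeletal muscle formation, the intestinal factor Isx and the ligand gene Wnt8b, the last with a promoter peak in each replicate list but none in the replicated list (the 4 were named after their values were seen). Adjusted p-values of the 5 lists ran from 2.6e-27 to 2.8e-12 (two-sided Fisher's exact test, 24 lists), and with rotation over gene order the adjusted p was 0.00060 for each.

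Peaks over these developmental genes were also strong and wide. Within the HOX list the highest folds were at Hoxd11 (16.1 ± 0.348, SD, n = 2, as for all folds that follow) and Hoxd8 (15.9 ± 0.307). Olig2, a factor of oligodendrocyte and motor neuron precursors, had a fold of 18.2 ± 0.176 under a peak of 16376 bp on chromosome 16 (91218693 to 91235068). Pou4f1, a factor of sensory neurons, had 17.4 ± 2.21, and the eye and brain factor Pax6 had 13.0 ± 2.30. Among mesodermal factors Tbx1 had 18.3 ± 0.220 and Tbx2 had 18.2 ± 0.385, the latter under a peak of 22000 bp on chromosome 11 (85825228 to 85847227), the widest of the replicated list. Among factors of other endodermal organs the thyroid factor Foxe1 had 17.6 ± 1.05 and the endocrine factor Insm1 had 17.4 ± 0.578, while the pancreatic factor Pdx1 had 9.51 ± 1.23. Among ligands Wnt3a had 20.5 ± 3.92 and Fgf8 had 15.9 ± 0.200. The median fold of the neural factor genes was 11.2 in replicate 1 and 13.9 in replicate 2, against 6.21 and 6.99 for the 4671 marked genes outside all lists. Their median domain width was 22.8 kb, against 3.22 kb outside the lists. For marked genes of the other lists it was 131 kb (HOX), 18.1 kb (mesodermal and limb factors), 14.9 kb (other endodermal factors) and 7.12 kb (signalling genes).

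Genes of excitable cells were also marked in most cases. Of 32 genes of neuronal function 28 were marked (87.5%), led by the neuronal splicing factor Rbfox3 (13.5 ± 0.554) and the vesicular GABA transporter Slc32a1 (12.9 ± 1.85), and of 26 ion channel genes 24 were marked (92.3%), led by the calcium channel genes Cacna1c (16.9 ± 1.69) and Cacna1g (15.0 ± 0.0462). Adjusted p was 1.0e-13 and 4.6e-13 (Fisher's exact test). The mark on Cacna1c lay at an internal promoter and was lost when the 5′ end of the gene alone was counted. The strongest peak of Rbfox3 also lay at an internal promoter, 339 kb from its 5′ end, which had a fold of 12.3 ± 0.343. Muscle contractile genes were marked in 7 of 28 cases (25.0%, adjusted p = 0.898 by Fisher's exact test), with the highest folds at the cardiac calcium channel gene Ryr2 (14.6 ± 3.07) and the skeletal actin gene Acta1 (8.66 ± 2.80). Keratinocyte genes were marked in 4 of 20 cases (Lor 7.99 ± 2.34, Perp 5.84 ± 1.65) and germline genes in 3 of 22 (Dmc1 4.58 ± 0.739, Tdrd1 3.86 ± 1.18), with an adjusted p of 1 and 0.537 by Fisher's exact test.

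**Figure D2:**
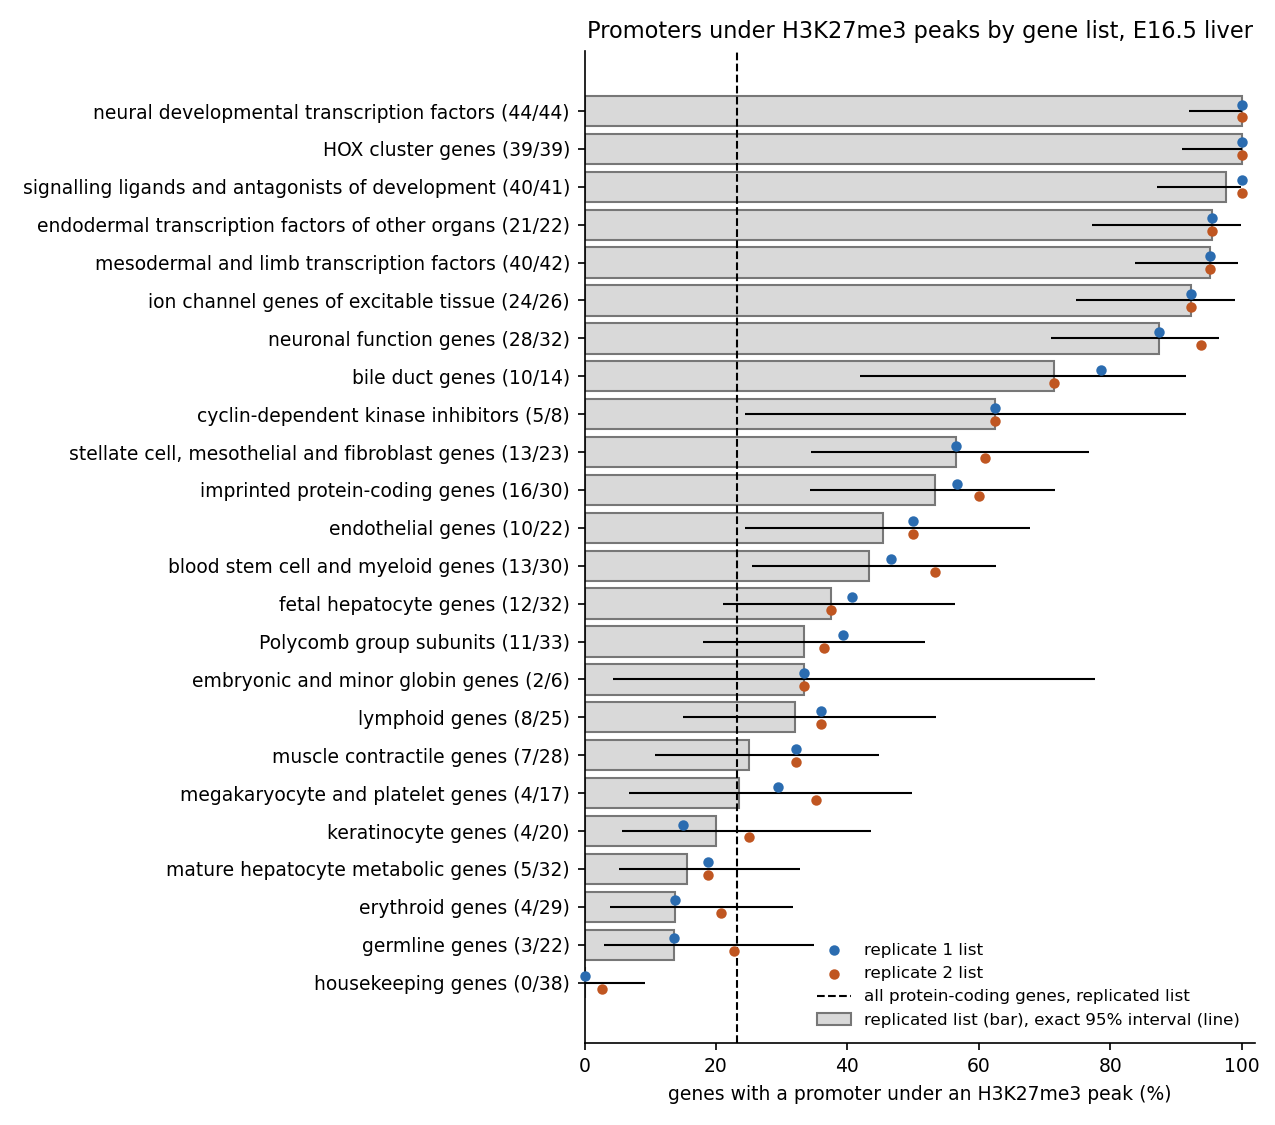
Share of genes in each list with a promoter under a peak (%), with bars for the replicated list, lines for its exact (Clopper-Pearson) 95% interval and points for each replicate list. The dashed line is the share of all protein-coding genes (23.2%), and the lists run from 0 of 38 housekeeping genes to 44 of 44 neural transcription factor genes.

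Several genes that define hepatocytes and erythroid cells had promoters without a peak. Alb and Afp, which encode the main plasma proteins of the adult and the fetus, had no promoter peak in any of the replicate 1, replicate 2 and replicated lists. The same was true of the hepatocyte factor Hnf4a, of Gata1 and Klf1, which drive red cell formation, of the alpha globin gene Hba-a1, of the bile acid enzyme gene Cyp7a1, of the Polycomb methyltransferase gene Ezh2, and of Actb and Gapdh. Of the genes named so far in this paragraph, only Ezh2 and Actb had a CpG-rich promoter. Genes without one were marked in 12.5% of cases, so a missing peak is usual for them and does not set liver or red cell genes apart. None of the 38 housekeeping genes was marked in the replicated list (95% interval 0 to 9.25%, Clopper-Pearson; adjusted p = 1.9e-04, Fisher's exact test), and 1 was marked in the replicate 2 list. Erythroid genes were marked in 4 of 29 cases (13.8%, adjusted p = 0.391) and mature hepatocyte metabolic genes in 5 of 32 (15.6%, adjusted p = 0.510), neither of which passed the threshold of Fisher's exact test. The marked erythroid genes with the highest folds were the membrane skeleton gene Ank1 (16.4 ± 0.187) and the blood stem cell factor Tal1 (3.76 ± 0.413, under a peak of 207 bp). Among mature hepatocyte genes these were the glutaminase gene Gls2 (14.1 ± 3.71) and the glucokinase gene Gck (5.03 ± 0.680). The marks on Tal1 and Gck lay away from the 5′ end of the gene and were lost when that end alone was counted. Of 6 embryonic and minor globin genes 2 were marked, Hba-x (4.15 ± 0.915) and Hbq1a (3.62 ± 0.413), and neither mark remained with a promoter window of 0.5 kb.

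Fetal hepatocyte genes were marked in 12 of 32 cases (37.5%; adjusted p = 0.098 by Fisher's exact test), which did not pass the threshold. The highest folds were at Onecut2 (13.3 ± 2.29) and Hhex (12.8 ± 0.998), both homeobox factors of early liver formation. Among CpG-rich promoters alone all 11 of the list's members were marked, and there the adjusted p was 1.2e-05. Over the 12 alternatives tried the adjusted p of this list ran from 1.2e-05 to 0.269, and the call was made in that setting only.

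Markers of some of the less abundant cells of the liver, those of bile duct, stellate and related cells and endothelium, were marked more often than other genes. Bile duct genes were marked in 10 of 14 cases (71.4%; Fisher's exact test, adjusted p = 4.7e-04), with Epcam, an epithelial adhesion gene, at 10.6 ± 3.39 and the duct factor Sox9 at 9.20 ± 2.18. Stellate cell, mesothelial and fibroblast genes were marked in 13 of 23 cases (56.5%; Fisher's exact test, adjusted p = 0.0013), with the stellate cell factor Lhx2 at 14.9 ± 0.0949 (12.8 ± 2.17 at its 5′ end) and the growth factor receptor gene Pdgfra at 13.4 ± 0.101. Endothelial genes were marked in 10 of 22 cases (45.5%; Fisher's exact test, adjusted p = 0.036), led by the factor Sox18 (13.1 ± 1.42) and the Notch ligand gene Dll4 (13.0 ± 2.19). The call for endothelial genes was lost under 4 of 12 alternatives, with an adjusted p of 0.071 by rotation over gene order (a permutation test) and a range over the alternatives of 0.0014 to 0.114. Other markers were unmarked, such as Pecam1, Cdh5, Tek, Col3a1, Dcn and Spp1 (named after their values were seen). Among CpG-rich promoters 9 of 10 bile duct, 7 of 7 stellate and related and 8 of 9 endothelial genes were marked. So were all 11 fetal hepatocyte genes of that class, so there these lists did not stand apart from hepatocyte genes.

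Blood stem cell and myeloid genes were marked in 13 of 30 cases (43.3%; adjusted p = 0.031, Fisher's exact test). The highest folds were at the stem cell factor Gata2 (17.3 ± 1.77) and the granulocyte factor Gfi1 (13.6 ± 1.90). Spi1, which directs myeloid and B cell formation, was marked in the replicated list by a peak of 236 bp that overlapped a peak in replicate 2 (fold 4.10) and none in replicate 1, and this mark was lost when the 5′ end of the gene alone was counted. The call for this list was lost under 3 of 12 alternatives, with a highest adjusted p of 0.126 (Fisher's exact test). Megakaryocyte and platelet genes were marked in 4 of 17 cases (Gp1bb 15.1 ± 2.94, Itgb3 8.26 ± 1.96; adjusted p = 1) and lymphoid genes in 8 of 25 (Bcl11b 13.3 ± 1.79, Tbx21 13.1 ± 1.40; adjusted p = 0.455, Fisher's exact test). Among CpG-rich promoters alone 6 of 7 lymphoid genes were marked, with an adjusted p of 0.0096 by Fisher's exact test.

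Imprinted genes, which are used from the allele of one parent, were marked in 16 of 30 cases (53.3%; adjusted p = 8.1e-04, Fisher's exact test), led by Dio3 (12.9 ± 3.22) and the growth factor gene Igf2 (12.8 ± 2.76, chromosome 7, peak at 142662265 to 142665976). The peak lists do not separate the alleles. Of 8 cyclin-dependent kinase inhibitor genes, which hold back cell division, 5 were marked, with Cdkn2a at 11.5 ± 1.13 and Cdkn1c, which is also in the imprinted list, at 10.4 ± 0.636. The adjusted p of this small list was 0.036 by Fisher's exact test, and the call was lost under 6 of 12 alternatives (range 0.029 to 0.508; 0.082 by rotation over gene order). Of 33 genes for Polycomb subunits 11 were marked (33.3%; adjusted p = 0.319, Fisher's exact test), led by Pcgf5 (13.8 ± 1.80) and Cbx8 (12.5 ± 1.44), and with a promoter window of 2.5 kb the adjusted p was 0.041 (range over alternatives 0.041 to 0.887). In sum over the 24 lists, 13 were marked more often than other genes and 1 less often by Fisher's exact test, and 11 and 1 with rotation over gene order, where endothelial genes and cyclin-dependent kinase inhibitors lost the call.

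Among genes outside the lists Onecut3, a homeobox factor gene, had the highest mean fold over its promoters (23.3 ± 1.08, chromosome 10, peak at 80488533 to 80499334), followed by Ccdc177 (21.5 ± 1.00), the neural crest homeobox gene Tlx2 (21.02 ± 1.71), Ppm1n (19.9 ± 1.93), the beta cell factor Mafa (19.7 ± 2.22) and Tpbgl (19.6 ± 3.34). The adjacent homeobox genes Hmx2 and Hmx3 shared a peak of 19110 bp and a fold of 19.3 ± 1.20. Ddn, a gene of the neuronal synapse, had 18.6 ± 0.211 and the synaptic adhesion gene Lrrc4b had 18.3 ± 3.21.

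Chromosome X carried far fewer peaks in replicate 1 than in replicate 2. Replicate 1 had 732 peaks on X (4.28 per Mb) and replicate 2 had 5642 (33.0 per Mb), a ratio of 7.71, where the ratio on the 19 autosomes lay between 1.23 and 1.43. The difference on X was thus larger than on any autosome, and the mean over replicates of 3187 ± 3471.9 X peaks (SD, n = 2) describes neither pool. In the replicated list X had 3.38 peaks per Mb, 0.372 of the autosome median and the lowest of 20 chromosomes, with the replicate 1 list giving 0.321 and the replicate 2 list 1.76. By covered bases X had 2.09 kb per Mb in replicate 1 and 10.4 in replicate 2, the latter 0.866 of the autosome median and rank 12 of 20 chromosomes. An exact rank test of X against 19 autosomes cannot reach a two-sided p below 0.1, so none is given. By number of peaks X thus lay above the autosome median in replicate 2 and by covered bases below it, so its direction depended on the measure. Of 948 X genes 132 (13.9%) were marked in the replicated list against 23.7% of autosomal genes. This resembled replicate 1 (13.7% against 24.8%) and was not seen in replicate 2, where 27.1% of X genes and 26.8% of autosomal genes were marked. The pooled list, called on both replicates together, held only 924 X peaks (5.40 per Mb, 0.489 of the autosome median). Of these 62.6% were kept in the replicated list, against 79.2 to 83.8% of pooled peaks on autosomes. Most X peaks of replicate 2 thus had no counterpart in number in the pooled list.

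**Figure D3:**
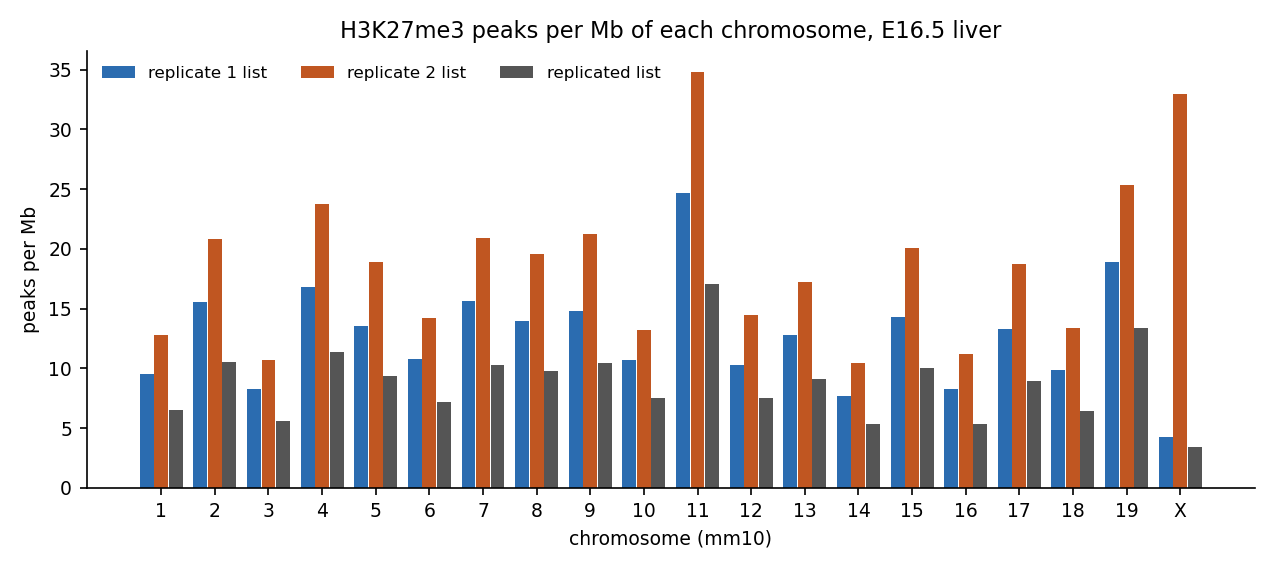
Peaks per Mb on each chromosome for the replicate 1, replicate 2 and replicated lists (bars, 1 value each, no error). Chromosome X stands at 4.28 in replicate 1 and 33.0 in replicate 2, while every autosome differs by a ratio of 1.23 to 1.43.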

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

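The alternatives with autosomes alone, the 5′ end of each gene, peaks that both replicate lists overlap and equal numbers of peaks were chosen after the data had been seen. The overlap of replicate 1 with replicate 2 (68.6 to 81.8%), the rho between replicates (0.586 to 0.682), the promoter share of peaks (21.4 to 50.4%), the number of protein-coding promoters marked (4447 to 5811) and the higher share of CpG-rich promoters kept their direction, and where tested their side of the threshold, under every alternative run. The median domain width moved from 2336 bp to 1699.5 bp with joining within 1 kb and to 2752 bp within 10 kb, as the joining distance sets it. With the list of one replicate alone it was 1136 to 1539.5 bp. The density of peaks on X relative to the autosome median, 0.372, was 0.321 with the replicate 1 list alone and 0.489 with the pooled list. It was 1.76 with the replicate 2 list alone, and 1.19 there with as many strongest peaks as replicate 1. By number of peaks its direction thus turned only with the replicate 2 list alone, and the cause was not tested there. By covered bases the replicate 2 list gave 0.866, below the autosome median as in the replicated list (an alternative also added after the data had been seen). The lower marked share of X genes than of autosomal genes was likewise absent from the replicate 2 list (27.1% against 26.8%). Of 287 results of single gene lists under 12 alternatives, 271 stayed called or not called as before, 13 lost the call, 3 gained one and 0 changed direction after a call. Some lists without a call did change direction, such as embryonic and minor globin genes with a promoter window of 0.5 kb. The 13 losses fell on cyclin-dependent kinase inhibitors (6), endothelial genes (4) and blood stem cell and myeloid genes (3), and the gains on Polycomb subunits (2.5 kb window) and on fetal hepatocyte and lymphoid genes (CpG-rich promoters only). Embryonic and minor globin genes have no CpG-rich promoter, so that setting gave no value. Of 115 named genes 13 changed their call under at least 1 of the 9 alternatives for single genes. Depth is unknown, so absence of a peak gives no upper limit on the mark.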

Other observations

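Several analyses here were chosen only after the main results had been seen. These were the tests of gene families, the values of long noncoding genes and of domains without a promoter, and the split of hepatocyte genes by CpG content. The test of hepatocyte factors among CpG-rich promoters and the form of the test of X dose were also chosen then. So were the tests of strong X sites and of X-linked genes, which replaced 2 tests written beforehand. Among 255 families of at least 10 genes that share a symbol stem, 42 were marked more often and 37 less often than other genes (Fisher's exact test, Benjamini-Hochberg over families), and 33 and 16 with rotation over gene order. All members were marked in the Nkx (14 of 14), Hoxa (11 of 11) and Hoxb (10 of 10) families of homeobox genes, of which the fixed lists held 9, 11 and 10. Other marked families were Wnt (18 of 19, adjusted p = 4.8e-09), Fzd for Wnt receptors (9 of 10, 2.2e-04), Cacna for calcium channels (12 of 14, 2.5e-05), Sox (16 of 19, 1.2e-06), Fgf (17 of 22, 3.5e-06), Sema for guidance factors (15 of 20, 2.5e-05) and Col for collagens (29 of 45, 2.2e-07), each by Fisher's exact test. Of 17 Syt genes for vesicle calcium sensors 15 were marked (adjusted p = 1.1e-06, Fisher's exact test). Some of these families share members with the fixed lists, 14 for Wnt, 9 for Sox, 7 for Cacna, 7 for Fgf, 3 for Col and 1 for Syt. Fzd and Sema share none.

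Receptor families of the nose and some families that all cells use had almost no promoter peaks. Of 1134 odorant receptor genes (Olfr) 3 were marked and of 331 vomeronasal receptor genes (Vmn) 0, with adjusted p-values of 2.7e-125 and 9.2e-37 by Fisher's exact test, which treats neighbouring genes as independent, and 0.0023 for each by rotation. Mitochondrial ribosomal protein genes (Mrpl) were marked in 0 of 49 cases (adjusted p = 6.4e-05, Fisher's exact test). Promoters of 9603 long noncoding genes (lincRNA, antisense and related annotated classes) were marked in 12.2% of cases. The share was 5.87% for the 7447 whose promoter lay apart from protein-coding promoters. Among domains, 3348 of 8254 (40.6%) overlapped no protein-coding promoter. These were narrow, with a median of 0.960 kb against 3.21 kb for the others, but 15 were at least 20 kb wide, among them 55.6 kb of chromosome 13 (45201184 to 45256809).

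Chromosome X carried 7.71 times as many peaks in replicate 2 as in replicate 1. A deeper library or looser threshold in replicate 2 is argued against as the whole cause. With equal numbers of strongest peaks the ratio on X was 3.40 and at most 1.06 on an autosome. The ratio on X did fall from 7.71 under this matching, so a part in the difference is not excluded. Strong discrete sites on X stay open, since peaks missing in one replicate are weaker by selection. The 5163 X peaks without a replicate 1 peak had a median fold of 3.35, against 3.18 for autosomal peaks of the same kind. This difference was 0.178 (95% interval 0.0308 to 0.203). Relative to X peaks with a replicate 1 peak, those without were weaker (-1.02, 95% interval -1.16 to -0.812). They were also narrower (median 221 against 507 bp) and less often over a promoter (6.47% against 38.2%). Both intervals come from resampling single peaks of replicate 2, which treats neighbouring peaks as independent. They are therefore too narrow to decide the question. A uniform difference in X dose also stays open: the added peaks were less dense over 6 genes that escape X inactivation than over other X genes (ratio 0.280, 95% interval 0 to 0.879), but 17.7% of random sets of 6 other X genes were as low, and although 46.4% of the added peaks lay in gene bodies that make up 26.3% of X, and 96 of 172 bins of 1 Mb held one, a uniform dose need not add peaks evenly where the signal is uneven, and peaks shared by the replicates did rise more on X, though by little beside the change in number (median log2 ratio of replicate 2 to replicate 1 0.257, against 0.0994 to 0.162 on autosomes). H3K27me3 of the inactive X in a pool with more female embryos may contribute, but the labels do not give the proportions of the sexes. Of 40 X genes used by most cell types, 7 had a promoter peak in replicate 2 alone and 0 in replicate 1 alone. The exact McNemar test, which treats genes as independent, gave p = 0.016. Of 35 autosomal housekeeping genes 1 had a promoter peak in replicate 2 and 0 in replicate 1. Among X genes unmarked in replicate 1, these 7 of 40 stood against 123 of 772 other X genes (odds ratio 1.12, 95% interval 0.408 to 2.65). The gain was thus seen on X but was not shown to differ between the 2 kinds of X genes, so these explanations cannot be told apart.

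Promoters of hepatocyte transcription factor genes carried peaks although hepatocytes use these genes, with 9 of 12 marked, namely Foxa1, Foxa2, Foxa3, Cebpa, Prox1, Onecut1, Onecut2, Nr5a2 and Hhex, which are named after their values were seen. The split within the fetal hepatocyte list followed CpG content, with 9 of 9 CpG-rich factor genes and 2 of 2 other CpG-rich genes marked, against 0 of 3 and 1 of 18 of the rest, so being a factor gene and having a CpG-rich promoter cannot be separated there. Peaks that only reach the edge of the promoter window are argued against, since 100% of the 9 had a replicated peak over a transcription start. Of all genes with a CpG-rich promoter 32.8% were marked, and the lower 95% bound of the odds ratio of the factor genes among them was 4.05. The factor genes were picked from a pattern seen in these same marks, so that bound carries little weight. In the fetal hepatocyte list, fixed beforehand, all 11 genes with a CpG-rich promoter were marked (adjusted p = 1.2e-05, Fisher's exact test). For that list, this argues against marking of CpG-rich promoters at the general rate as the whole cause. It is not separate evidence for the factor genes, since 9 of these 11 are the same genes. The list was also called in this setting only. CpG-rich members of the neural factor list were likewise all marked (42 of 42), so the marking was not particular to hepatocyte factors. A mixture of unmarked hepatocytes with marked blood, endothelial and other cells may account for the peaks, but the test was not decisive: the mean fold over these genes differed from that at 44 marked neural factor genes by -2.29, with permutation p-values of 0.079 in replicate 1 and 0.023 in replicate 2. Mixed cells and partial marking within hepatocytes cannot be told apart in whole tissue.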
